A study of Saccharomyces cerevisiae with 40 samples.

How the data were processed

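Messenger RNA of budding yeast, Saccharomyces cerevisiae, was measured on 40 one-colour Affymetrix arrays that the labels place in 16 groups. Total RNA was taken at mid log phase after 18 generations of growth without stress, per the labels' protocols. Poly(T) primers were used for the cDNA, so the measurement covers polyadenylated transcripts. The deposited values are on the log2 scale and were made by the authors with RMA, a method that corrects background, quantile-normalizes arrays and combines the probes of a probe set, per the submitters' processing notes. The version of RMA and the arrays that were normalized together are not given in the sources used here. Values ran from 2.10 to 15.1, and array medians from 5.31 to 6.84. Scanner files were not used here, so the background correction and the summary of probes could not be repeated.

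Quantile normalization of arrays together leaves identical values on different arrays, and the table was searched for them. Arrays were joined in a set where at least 0.1% of values were identical to the last digit. This gave 9 sets. Each array with a partner shared at least 0.220% of its values with the closest array of its set, and arrays of different sets shared at most 0.0183%. The sets stand for normalization runs and were inferred from the values, not from the labels. Set 1 held ancestor array 1, abrupt-heat replicate 2, the trisomic and monosomic clones and the 4 arrays kept at 30 °C after heat. Set 2 held abrupt-heat replicates 1 and 3, set 3 held abrupt-heat replicate 4 and 30 °C replicate 1, and set 4 held 30 °C replicate 2 alone. Set 5 held ancestor array 2 and the 4 gradual-heat arrays, and set 6 the 5 arrays on minimal medium. Set 7 held haploid ancestor 1 and the 4 arrays after 750 generations at high pH, set 8 the pH array after 150 generations and both pH spores, and set 9 haploid ancestor 2 and the 8 spores of the 39 °C line.

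The array holds 10928 probe sets. The platform annotation gives 1 gene name for 7244 of them, several for 1 and none for 3683. By gene number, 5498 probe sets were matched to 5449 genes of the R64 gene table, which was used for names, chromosomes and the order of neighbouring genes. For the 47 genes with more than 1 probe set, the probe sets were averaged, and the one with the highest mean was an alternative. Probe sets named for another species, 1746 in all, served as background. The 95th percentile of their values on each array, 4.23 to 5.36, was the level a gene had to exceed to be called above background. A gene was tested where it exceeded background on at least 2 arrays. Where a gene was below background in every array of 1 group, the change is given as "at least N-fold" against the background level, and no fold is given where both groups were below it.

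Genes were tested with limma 3.58.1 in R 4.3.3, using a trended prior variance and Benjamini-Hochberg adjustment at an adjusted p threshold of 0.05. The fit of the 23 diploid arrays covered 5335 genes with 9 residual degrees of freedom. The fit of the 17 haploid and spore arrays covered 5352 genes with 10. All groups of a fit shared one estimate of the spread. The design fixed before the data were examined had no term for the sets, since the labels do not name them. After the sets were seen, fits with no set term, with a fixed term and with a random term were run, and the fixed term was adopted after their counts were known, because values of separately normalized sets do not share a scale. The count without a set term is given beside each count. With the fixed term a comparison rests on the sets that hold both of its groups, or on a chain through another group, so several contrasts come down to 1 array against 1 or 4 against 1. A lone array is then assumed to vary like the replicated groups. Errors of fitted changes are standard errors (SE) from limma, and n gives the arrays that carry the contrast.

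A set of 25 gene lists was fixed before the data were examined. They were heat shock chaperones, the general stress response of Msn2 and Msn4, ribosomal proteins, ribosome biogenesis, cell wall integrity, amino acid biosynthesis under Gcn4, methionine and sulfur assimilation, the phosphate (PHO) regulon, iron and copper uptake, alkaline pH and calcineurin, the vacuolar ATPase, oxidative phosphorylation, the TCA and glyoxylate cycle, glycolysis and fermentation, hexose transporters, the proteasome, ergosterol, thiamine, uracil and purine biosynthesis, amino acid permeases and nitrogen, common auxotrophic markers, meiosis and sporulation, and a-specific, alpha-specific and haploid-specific genes. With the 16 chromosomes they made 41 lists, tested with camera at a preset correlation of 0.01 and again with the estimated correlation. They were also tested with fry, which asks whether the genes of a list move, on balance, one way, and does not set them against other genes. A list was called where camera's adjusted p over the 41 lists passed 0.05. Members were also tested with p-values adjusted over the list alone.

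The value of a chromosome on an array was the median over its genes of the difference from the mean of the fit, or the difference from the ancestor array of the same set. Abrupt-heat replicate 4 was set against 30 °C replicate 1 of its set, the pH arrays of set 8 against the euploid spore, and arrays with no such partner against the mean of both ancestor arrays. Groups were compared on these values by two-sided exact permutation tests with adjustment over 16 chromosomes. Running medians over 21 neighbouring genes were searched for stretches beyond 0.4 in log2. Comparisons of single clones or spores with 1 array a side were described without a test, as the design laid down, although the fit with the set term would have allowed one. Instead, a list's median was ranked among 10000 random lists of its size from 20 bins of mean expression, ignoring correlation within lists. Comparisons with the ancestor, of abrupt heat with 30 °C and gradual heat, and of the line kept at 30 °C with abrupt heat were fixed before the data were examined. Comparisons of that line with the ancestor and of the 2 minimal-medium groups were added later.

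Genes were named by a rule fixed beforehand. Called genes were ranked by the size of the change, with the 10 highest and 10 lowest named for abrupt heat against ancestor, abrupt against gradual heat, high pH and the 39 °C spores, and the 5 highest and 5 lowest for other comparisons. Where none was called, the 3 smallest p-values each way were named. For each called list, up to 3 called members with the largest change in its direction were named, or the 2 largest as values where none was called. For single clones and spores, the 3 largest changes among each mating-type list and the 5 largest each way were named. Per-array values of ECM1, YAP3, IME4, FRE7, CTR1, FRE1 and PHO89 and the stretches of neighbouring genes were chosen after their values were seen.

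Data simulated with real means, layout and fitted spreads tested the fits, not how a lone array varies. Of 100 genes shifted by 1 in log2, limma recovered 95% for abrupt and 94% for gradual heat against ancestor. It recovered 76% for 30 °C, and 94% and 76% for abrupt heat against 30 °C and gradual heat. It recovered 97% for the line kept at 30 °C against abrupt heat, 96% and 93% for the H2 and trisomic lines on minimal medium, 94% for high pH and 93% for the spores. A separately simulated chromosome shift of 0.5 gave 0.49 for abrupt against gradual heat, set differences untested.

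Alternatives were a fit of the compared groups alone or of all arrays, array weights, no trend, no filter on dim genes or a filter on the mean, quantile normalization repeated over all arrays, centring on the median, another rule for several probe sets, the replicate number as a block, and each array left out in turn. Replicates are not always labelled separate cultures, so p-values measure the spread of these samples. With the set term, lone arrays add none. Few arrays limit precision. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.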

Results

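Transcript levels were measured in yeast populations after long growth under a constant stress, in clones with an altered chromosome number and in spores of evolved lines. The diploid arrays comprised 2 of the ancestor, 4 after 450 generations at 39 °C applied abruptly, 4 after 450 generations of heat raised gradually from 30 °C to 39 °C, and 2 after 450 generations at 30 °C. Unevolved clones with 3 copies or 1 copy of chromosome III had 1 array each. A line named H2, derived from abrupt heat, had 4 arrays after another 600 generations at 30 °C and 2 after another 1000 generations at 39 °C on minimal medium. The trisomic clone had 2 arrays after 1000 generations at 39 °C on minimal medium, and the ancestor 1 array on that medium. The haploid arrays comprised 2 of the ancestor, 1 after 150 generations at pH 8.6, 4 after 750 generations at that pH, a euploid and a disomic spore of the pH line with 1 array each, and 8 spores of a line evolved at 39 °C. All cells had grown for 18 generations without stress before RNA was taken, so the comparisons address lasting changes rather than an immediate response.

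Replicates differed in their closeness. The standard deviation, over genes, of the log2 difference between 2 arrays was 0.0571 to 0.0949 among gradual-heat arrays, 0.179 to 0.244 among H2 arrays kept at 30 °C and 0.0853 to 0.241 among arrays after 750 generations at pH 8.6. Among spores of the 39 °C line it was 0.129 to 0.472. Abrupt-heat arrays of different normalization sets differed by 0.372 to 0.477, against 0.220 for the pair within a set. The 2 diploid ancestor arrays, of different sets, differed by 0.372, and the 2 haploid ancestor arrays by 0.462.

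Chromosome III, whose genes include the silent and expressed mating-type loci, was higher in every abrupt-heat array. The unevolved trisomic clone lay at 0.49 in log2 over ancestor array 1 and the monosomic clone at −0.51. In size the latter fell short of the 0.76 of chromosome V in the haploid disomic spore, although both are changes between 1 copy and 2. The abrupt-heat arrays lay at 0.45, 0.50, 0.45 and 0.51. Their mean on the centred scale was 0.38 ± 0.04 (SD, n = 4), against −0.09 ± 0.01 (SD, n = 4) in the ancestor and 30 °C arrays. The difference of 0.47 had p = 0.0286 in an exact permutation test, the smallest that 70 arrangements allow. The gradual-heat arrays stood at −0.12 ± 0.01 (SD, n = 4). Abrupt heat exceeded them by 0.50, in 4 of 4 arrays (exact permutation p = 0.0286). The H2 arrays after 600 generations at 30 °C stood at −0.10 ± 0.01 (SD, n = 4), a difference of −0.48 from abrupt heat (exact permutation p = 0.0286). Adjusted over 16 chromosomes these p-values became 0.152, 0.0914 and 0.152, so none passed the adjusted threshold with 4 arrays a side. Within the normalization sets that hold both groups, the first and last differences were 0.50 and −0.51. Some other chromosomes reached the same smallest p with differences of 0.07 or less in size. Both minimal-medium groups lay near the ancestor on that medium, at −0.07 and −0.06 in the H2 arrays and −0.06 in each array of the trisomic descent.

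**Figure D1:**
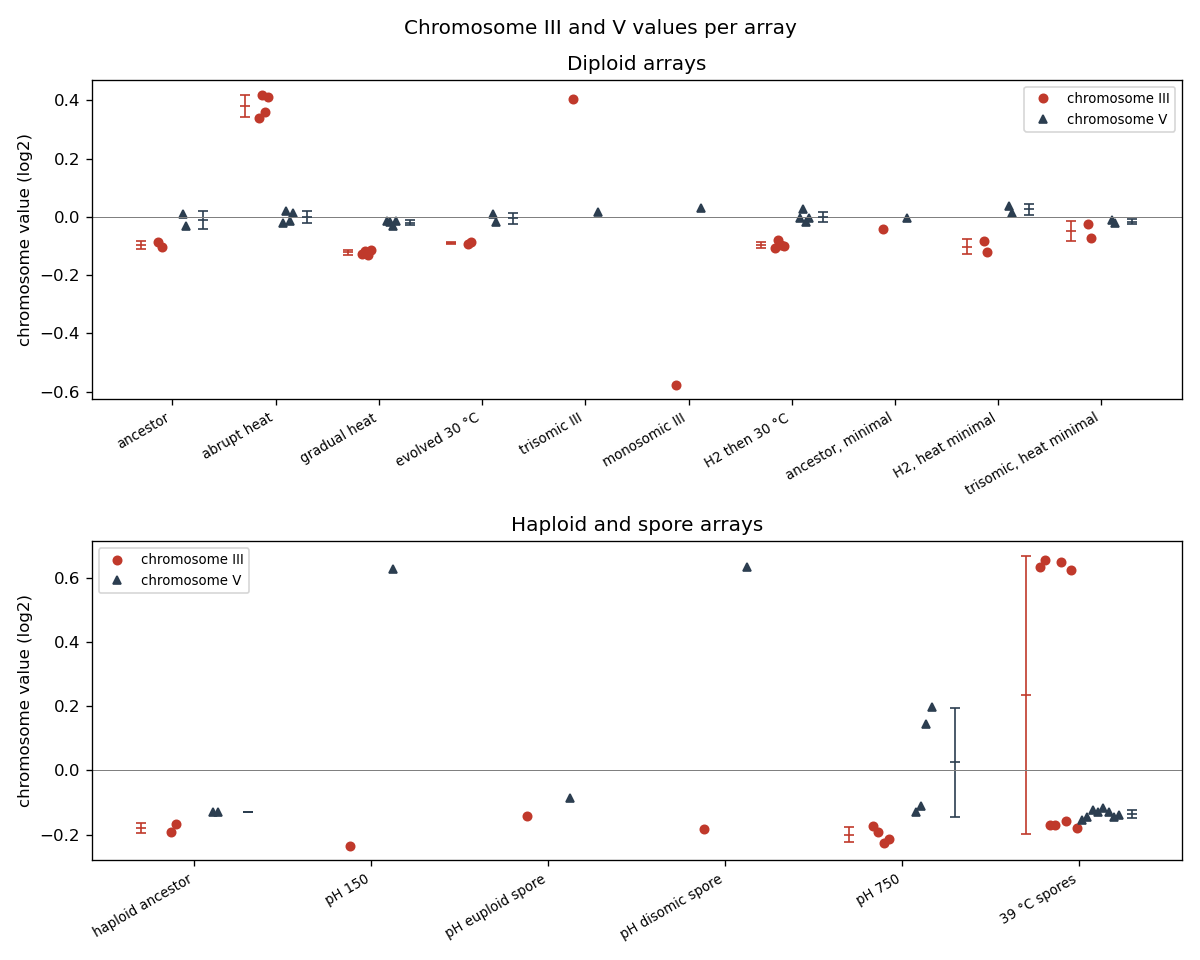
Chromosome III (circles) and chromosome V (triangles) values of each array, as the median log2 difference of the chromosome's genes from the mean of the fit, for diploid arrays above and haploid and spore arrays below, with bars for mean ± SD beside groups of 2 or more arrays. Abrupt-heat arrays averaged 0.38 on chromosome III against −0.12 in gradual heat, and the 8 spores of the 39 °C line averaged 0.24 with an SD of 0.43.

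Abrupt heat was compared with the ancestor after 450 generations at 39 °C. YGP1, which encodes a secreted glycoprotein of the cell wall, rose by 2.90 ± 0.52 in log2 (SE, n = 1 against 1; adjusted p = 0.0376), and SPI1, a wall protein of stationary phase, by 1.54 ± 0.27 (adjusted p = 0.0327). BNA4 of NAD synthesis rose by 1.06 ± 0.14 and LYS2 of lysine synthesis by 0.85 ± 0.10. The homocysteine synthase gene MET17 was at background, at least 78.4-fold below the ancestor (adjusted p = 1.9e-12), and the ribosomal protein gene RPS14B fell by 0.66. MET17 was above background on 7 of 40 arrays, and its changes and those of LYS2 may be of marker genotype. The unevolved trisomic clone, 1 of the 7, had YGP1 at 2.78, SPI1 at 1.71 and RPS14B at −0.74 over the same ancestor array. The other 6 of the 10 genes with the largest rise all lie on chromosome III: BUD3 of bud-site selection at 0.79, the corepressor gene TUP1 at 0.71 ± 0.11, POF1 at 0.65, TAF2 of TFIID at 0.61, DCC1 of sister chromatid cohesion at 0.61 and YCL012C at 0.60.

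With the set term, limma called 14 genes higher and 2 lower, 10 of the 14 on chromosome III. Without that term it called 21 higher and 1 lower, with 3 genes shared and a median over all genes of 0.43. A fit of the compared groups alone called 0 genes, all arrays in 1 fit 3, the set as a random term 57, array weights 331 and the ancestor and 30 °C arrays as 1 control 110. The contrast rests on abrupt-heat replicate 2 against ancestor array 1, the only set that holds both groups. Of the 145 genes tested on chromosome III, 142 had a positive change with a mean of 0.48 (camera adjusted p = 3.2e-120; adjusted p = 1.4e-09 with an estimated correlation). Of these, 10 were called over all genes against 110 adjusted over the list alone. Of the stress genes under Msn2 and Msn4, 28 of 29 had a positive change with a mean of 0.51 (camera adjusted p = 9.0e-07; adjusted p = 0.782 with an estimated correlation). Over all genes 2 were called, and 2 adjusted over the list alone. The heat shock chaperones averaged 0.19, with SSA4 at 0.95 ± 0.38 and BTN2 at 0.70 ± 0.57, and none of 27 was called on either scale (camera adjusted p = 0.00499; adjusted p = 0.782 with an estimated correlation). Glycolysis averaged 0.05, with TDH1 at 0.34 and PGK1 at 0.14, and 1 of 18 genes was called adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.782 with an estimated correlation). Amino acid permeases averaged 0.13, with AGP1 at 0.81 ± 0.22 and MEP1 at 0.48 (camera adjusted p = 0.0225; adjusted p = 0.457 with an estimated correlation). Oxidative phosphorylation genes averaged −0.12, with CYC1 at −0.56 ± 0.29 and COX4 at −0.31 ± 0.20 (camera adjusted p = 0.0204; adjusted p = 0.811 with an estimated correlation). The a-specific genes, which diploids keep low, averaged −0.57, with AGA2 at least 1.68-fold lower and STE2 at −0.96 ± 0.31, and 2 of 7 were called adjusted over the list alone (camera adjusted p = 0.000217; adjusted p = 0.570 with an estimated correlation).

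Gradual heat was compared with the ancestor in the same way. COS12, of a subtelomeric family with near-identical copies, rose by 2.91 ± 0.45 (SE, n = 4 against 1; adjusted p = 0.0285), YIR042C by 2.15 ± 0.27 (adjusted p = 0.00602) and LYS2 by 0.63 ± 0.08 (adjusted p = 0.00628). MET17 was at background, at least 161-fold below the ancestor (adjusted p = 1.0e-14). These 4 were the genes called by limma, with 37 higher and 37 lower at an unadjusted p under 0.05. A fit of the compared groups alone called 446, array weights 90 and all arrays in 1 fit 2. Without the set term it called 1 higher and 1 lower, and both were among the 4.

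Oxidative phosphorylation genes averaged 0.28 in gradual heat with all 37 positive, QCR10 at 0.60 ± 0.28 and the Rieske protein gene RIP1 at 0.53 ± 0.25 leading. None was called singly or adjusted over the list alone (camera adjusted p = 1.6e-26; adjusted p = 0.622 with an estimated correlation). The general stress list averaged 0.21, with GPH1 of glycogen breakdown at 0.89 ± 0.50 and HXK1 at 0.66 ± 0.54, and 22 of 29 were positive (camera adjusted p = 0.00361; adjusted p = 0.992 with an estimated correlation). Ribosomal protein genes averaged 0.02, with RPL27B at 0.14 and RPS14B at 0.13 (camera adjusted p = 6.5e-05; adjusted p = 0.992 with an estimated correlation). Amino acid biosynthesis genes under Gcn4 averaged −0.05, with CPA1 at −0.24 and ARO3 at −0.15, although LYS2 of that list rose (camera adjusted p = 0.00419; adjusted p = 0.914 with an estimated correlation). Proteasome genes averaged −0.05, with UFD1 at −0.15 and RPN4 at −0.14 (camera adjusted p = 0.00185; adjusted p = 0.914 with an estimated correlation). The a-specific genes averaged −0.27, with AGA2 at −0.58 and MFA2 at −0.51 (camera adjusted p = 0.0138; adjusted p = 0.914 with an estimated correlation). The 7 auxotrophic markers averaged −1.06, mostly through MET17, with LYS2 rising and the other 6 negative (camera adjusted p = 0.0283; adjusted p = 0.622 with an estimated correlation).

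Evolution at 30 °C was set against the ancestor. MET17 was at background there too, at least 86.5-fold below the ancestor (adjusted p = 2.0e-10). It was the 1 gene called by limma, with 120 higher and 110 lower at an unadjusted p under 0.05. YGP1 had a change of 3.96 ± 0.74 that did not pass (adjusted p = 0.253). Oxidative phosphorylation averaged 0.57 with 36 of 37 genes positive, CYT1 at 1.09 ± 0.52 and QCR10 at 1.03 ± 0.50 (camera adjusted p = 1.7e-19; adjusted p = 0.486 with an estimated correlation). Without the set term limma called 21 higher and 2 lower, with 1 gene shared, and with quantile normalization repeated over all arrays as well it called 206 higher and 215 lower. Array weights with the term gave 332, a random term 3 and all arrays in 1 fit 2. No set holds both groups, so abrupt-heat replicates 2 and 4 link them, and their difference enters each change.

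General stress genes averaged 0.69 at 30 °C, with DDR2 at 2.60 ± 1.00 and 3 called adjusted over the list alone (camera adjusted p = 1.4e-05; adjusted p = 0.854 with an estimated correlation). Ribosomal protein genes averaged 0.03, with RPS14B at 0.52 and RPS19A at 0.22 (camera adjusted p = 0.0113; adjusted p = 0.854 with an estimated correlation). Gcn4 targets averaged −0.21 with 35 of 39 negative, ARG1 at −1.16 ± 0.50 and ARG3 at −0.85 ± 0.44, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.5e-08; adjusted p = 0.292 with an estimated correlation). Thiamine genes averaged −0.17, with THI72 at −0.71 and THI22 at −0.65 (camera adjusted p = 0.0140; adjusted p = 0.207 with an estimated correlation). Uracil and purine genes averaged −0.19, with IMD2 at −1.01 ± 1.02 and ADE1 at −0.45 (camera adjusted p = 0.00223; adjusted p = 0.207 with an estimated correlation). The a-specific genes averaged −0.68, with STE2 at −1.53 ± 0.44 (camera adjusted p = 0.000890; adjusted p = 0.486 with an estimated correlation). The 4 alpha-specific genes averaged 1.01, with MF(ALPHA)1 at 2.33 ± 1.30 and MF(ALPHA)2 at 1.08 ± 0.37 (camera adjusted p = 0.0189; adjusted p = 0.503 with an estimated correlation).

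Abrupt heat was set against evolution at 30 °C to separate heat from time. CIT2, the peroxisomal citrate synthase gene on chromosome III, rose by 2.10 ± 0.24 (SE, n = 1 against 1; adjusted p = 0.00223). ARG1 and ARG3 of arginine synthesis rose by 2.02 ± 0.36 and 1.70 ± 0.31, SRD1 of chromosome III by 1.41 ± 0.29 and YNL195C by 1.32 ± 0.24. ARO10 and ARO9 of aromatic amino acid breakdown changed by −2.39 ± 0.42 and −1.60 ± 0.26. INH1, an inhibitor of the mitochondrial ATP synthase, changed by −2.06, and RPM2 of mitochondrial RNase P by −1.42. GAC1, a regulator of glycogen synthesis, dropped below background, at least 1.52-fold lower. With the set term limma called 63 genes higher and 18 lower, and 40 of the higher ones lay on chromosome III. The balance turned to 12 higher and 24 lower with all arrays in 1 fit, array weights gave 573 and 571, a random term 82 and 47, and the compared groups alone 0. The contrast rests on abrupt-heat replicate 4 against 30 °C replicate 1. Without the term it called 0 higher and 1 lower, which was shared, and with quantile normalization repeated over all arrays as well it called 176 higher and 182 lower.

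Chromosome III averaged 0.49 against 30 °C, with 140 genes positive, 40 called over all genes and 102 adjusted over the list alone (camera adjusted p = 1.0e-63; adjusted p = 2.8e-08 with an estimated correlation). Gcn4 targets averaged 0.29 with 38 of 39 positive, 6 called, among them LEU1 at 0.71 ± 0.12, and 10 adjusted over the list alone (camera adjusted p = 3.3e-12; adjusted p = 0.110 with an estimated correlation). Oxidative phosphorylation genes averaged −0.69 with 36 of 37 negative, 6 called and 29 adjusted over the list alone, including COR1 at −0.98 ± 0.22, COX4 at −0.96 ± 0.20 and ATP7 at −0.87 ± 0.17 (camera adjusted p = 1.8e-26; adjusted p = 0.256 with an estimated correlation). Thiamine genes averaged 0.27, THI22 rising by 0.76 ± 0.16, with 4 called adjusted over the list alone (camera adjusted p = 0.000360; adjusted p = 0.0342 with an estimated correlation). Amino acid permeases averaged 0.18, BAP2 rising by 0.45 ± 0.10, with 2 adjusted over the list alone (camera adjusted p = 0.00637; adjusted p = 0.110 with an estimated correlation). Ribosomal proteins averaged −0.04, with a change of −1.18 ± 0.11 in RPS14B (camera adjusted p = 0.0239; adjusted p = 0.972 with an estimated correlation). Iron and copper uptake averaged 0.17, with FRE7 at 0.75 and FRE1 at 0.73 (camera adjusted p = 0.0332; adjusted p = 0.780 with an estimated correlation). Glycolysis averaged 0.09, with ADH2 at 0.50 and PDC6 at 0.30 (camera adjusted p = 0.0295; adjusted p = 0.780 with an estimated correlation).

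Abrupt and gradual heat were compared directly, since both lasted 450 generations and ended at 39 °C. Chromosome III averaged 0.51 higher in abrupt heat with 142 of 145 genes positive (camera adjusted p = 6.7e-96; adjusted p = 4.2e-09 with an estimated correlation), and 0 of its genes were called over all genes against 85 adjusted over the list alone. Oxidative phosphorylation genes averaged −0.40 with 36 of 37 negative, QCR10 at −0.78 ± 0.45 and CYC1 at −0.73 ± 0.37 (camera adjusted p = 2.1e-15; adjusted p = 0.831 with an estimated correlation). Stress genes averaged 0.31, with SPI1 at 1.58 ± 0.34 and 2 called adjusted over the list alone (camera adjusted p = 0.0306; adjusted p = 0.831 with an estimated correlation). YGP1 stood at 2.89 ± 0.67. Gcn4 targets averaged 0.13, with ARG1 at 0.91 ± 0.45, ARG3 at 0.82 ± 0.39 and 2 called adjusted over the list alone (camera adjusted p = 0.00271; adjusted p = 0.831 with an estimated correlation). Permeases averaged 0.20, with AGP1 at 0.99 ± 0.27 and DAL3 at 0.69 ± 0.28 (camera adjusted p = 0.00271; adjusted p = 0.143 with an estimated correlation).

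In this direct comparison limma called 1 gene, MET17 (adjusted p = 0.050), which was below background in both groups so that no size is given, with 158 higher and 38 lower at an unadjusted p under 0.05. With no set term 2215 genes were higher and 5 lower, none of them the gene called with it, and the median over all genes was 0.51. With quantile normalization repeated over all arrays and no set term, 407 were higher and 324 lower, and with the set term the repeat and median centring each gave 0, a random term 4 and array weights 243. The groups share no set, so the set term joins them through the 2 ancestor arrays.

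The H2 line after 600 generations at 30 °C was compared with abrupt heat, the regime it came from. The labels do not say which abrupt-heat replicate, if any, H2 is, and the contrast rests on abrupt-heat replicate 2, so it holds any difference between lines as well as the time without heat. The acid phosphatase gene PHO11 rose by 1.39 ± 0.30 (SE, n = 4 against 1; adjusted p = 0.0382), HFM1 and SPS4 of meiosis and sporulation by 0.98 ± 0.16 and 0.93 ± 0.16, YOL014W by 0.92 ± 0.17 and RPS14B by 0.88 ± 0.08. SPI1 changed by −1.49 ± 0.21 (adjusted p = 0.00358) and YMR196W by −1.39 ± 0.17. The glucokinase gene GLK1 and ATG22, both of chromosome III, changed by −1.24 and −1.08, and MSC1 by −1.09. Of 145 genes on chromosome III, 142 were negative with a mean of −0.46, 68 fell over all genes and 118 adjusted over the list alone (camera adjusted p = 4.1e-102; adjusted p = 3.1e-09 with an estimated correlation). All 29 general stress genes were negative with a mean of −0.81, 4 fell over all genes and 14 adjusted over the list alone (camera adjusted p = 2.5e-19; adjusted p = 0.678 with an estimated correlation). Oxidative phosphorylation averaged −0.14, with COX5B at −0.76 and QCR8 at −0.32 (camera adjusted p = 0.000979; adjusted p = 0.821 with an estimated correlation). With the set term limma called 15 higher and 80 lower, and 61 in all without H2 replicate 3. The compared groups alone gave 1, all arrays in 1 fit 3, replicate and set blocks together 0, a random term 159 and array weights 480. Without the term it called 2 higher and 116 lower, with 48 shared. PHO11, SPS4 and YOL014W then had changes of −0.25, −0.13 and −0.14. With quantile normalization repeated as well it called 100 higher and 152 lower.

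Against the ancestor, the same H2 arrays had 2 genes higher and 2 lower. LYS2 rose by 0.98 ± 0.08 (SE, n = 4 against 1; adjusted p = 5.7e-05) and the acetyltransferase gene HPA3 by 0.50 ± 0.08. MET17 was at background, at least 81.2-fold below the ancestor (adjusted p = 8.5e-14), and ECM13 fell by 1.37. Stress genes averaged −0.30, with HSP12 at −2.06 ± 0.60 and SOL4 at −1.07 (camera adjusted p = 1.0e-07; adjusted p = 0.614 with an estimated correlation). Oxidative phosphorylation averaged −0.25 with all 37 negative, COX5B at −0.65 and QCR10 at −0.37 (camera adjusted p = 1.7e-16; adjusted p = 0.608 with an estimated correlation). Iron and copper uptake averaged 0.19, with FRE7 at 0.74, FIT1 at 0.55 and 2 called adjusted over the list alone (camera adjusted p = 0.00147; adjusted p = 0.614 with an estimated correlation). The vacuolar ATPase averaged −0.06, with VMA7 at −0.17 and VMA8 at −0.16 (camera adjusted p = 0.00147; adjusted p = 0.608 with an estimated correlation). Gcn4 targets averaged 0.11 with LYS2 alone called (camera adjusted p = 0.0142; adjusted p = 0.679 with an estimated correlation). Hexose transporters averaged −0.18, with HXT7 at −1.39 and MIG2 at −0.29 (camera adjusted p = 0.0449; adjusted p = 0.608 with an estimated correlation). The a-specific genes averaged −0.25, with AGA2 at −0.63 and MFA2 at −0.48 (camera adjusted p = 0.0249; adjusted p = 0.614 with an estimated correlation). With no set term 1 gene was higher and 1 lower, with 1 shared, against 202 higher and 94 lower at an unadjusted p under 0.05 with it. Repeated quantile normalization or median centring with the term gave 1 higher and 2 lower. Leaving out H2 replicate 4 gave 10 genes, the compared groups alone 1, a random term 9 and array weights 107.

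After 1000 generations at 39 °C on minimal medium, the H2 line was compared with the ancestor on that medium. The transcription factor gene SWI5 of late mitosis rose by 4.18 ± 0.15 (SE, n = 2 against 1; adjusted p = 1.8e-10), the cyclin genes CLB6 and PCL1 by 3.97 ± 0.15 and 3.91 ± 0.14, and HOF1 of cytokinesis by 3.59 ± 0.13. The hydrophilin gene GRE1 rose by 3.85 ± 0.20. MET17 was at background, at least 205-fold below the ancestor, and SRL4 changed by −5.67 ± 0.21. RTC2 changed by −5.36, SNO1 of vitamin B6 metabolism by −5.33 and FMP23 by −4.46. Of 39 Gcn4 targets with a mean of −1.55, 37 fell over all genes and 37 adjusted over the list alone, with ARG3 at −4.17 ± 0.27, ARG1 at −3.11 ± 0.31 and LYS1 at −3.02 ± 0.11 (camera adjusted p = 2.0e-21; adjusted p = 0.0547 with an estimated correlation). Ribosomal proteins averaged 0.17, with 79 rising, RPL41A by 1.15, RPL39 by 0.67 and RPL15B by 0.59, and 4 falling, against 81 and 4 adjusted over the list alone (camera adjusted p = 9.3e-07; adjusted p = 0.698 with an estimated correlation).

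Among smaller groups in the H2 line on minimal medium, ribosome biogenesis averaged 0.31, with 21 of 38 rising, HAS1 by 0.84, BRX1 by 0.79 and KRR1 by 0.72, and 22 adjusted over the list alone (camera adjusted p = 0.00964; adjusted p = 0.890 with an estimated correlation). The proteasome averaged 0.37, 24 of 34 genes rising on either scale, with RPT2 at 0.86, RPN8 at 0.74 and RPN7 at 0.64 (camera adjusted p = 2.2e-05; adjusted p = 0.365 with an estimated correlation). Iron and copper uptake averaged −0.49, 16 falling and 2 rising over all genes and adjusted over the list alone, with FIT1 at −1.99, COT1 at −1.53 and FRE6 at −1.39 (camera adjusted p = 0.00306; adjusted p = 0.698 with an estimated correlation). Thiamine genes averaged −0.64, with THI72 at −2.70, THI73 at −1.69 and THI2 at −1.45 (camera adjusted p = 0.0131; adjusted p = 0.107 with an estimated correlation). Permeases averaged −0.57, 16 falling, with CAN1 at −1.52, BAP2 at −1.46 and DIP5 at −1.30 (camera adjusted p = 0.000944; adjusted p = 0.0967 with an estimated correlation). Auxotrophic markers averaged −1.86, mostly through MET17, 5 falling, with LYS2 at −1.70 (camera adjusted p = 0.00226; adjusted p = 0.107 with an estimated correlation). Limma called 1633 higher and 1459 lower with the set term, and 249 and 259 without it, all 508 shared, and the compared groups alone gave 1338. The ancestor on minimal medium has 1 array, so its own deviation, such as −0.41 on the centred scale over the 30 genes from BAP2 to YBR096W, enters this comparison and the next.

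The trisomic clone after the same regime was compared with the same ancestor array. PCL1 rose by 3.26 ± 0.14 (SE, n = 2 against 1; adjusted p = 9.4e-09), CLB6 by 3.07 ± 0.15, SWI5 by 2.98 ± 0.15, HOF1 by 2.48 ± 0.13 and the repressor gene YOX1 by 2.45 ± 0.22. ECM1, of ribosomal subunit export, fell to background, at least 22.1-fold lower (adjusted p = 4.9e-09). The phosphate transporter genes PHO84 and PHO89 changed by −3.70 ± 0.40 and −3.01 ± 0.47, and the membrane protein gene HSP30 and TDA6 stood at −2.96 ± 0.36 and −2.73 ± 0.29. In the phosphate regulon, 9 of 18 genes fell and 1 rose with a mean of −0.78, SPL2 at −2.23, against 10 and 1 adjusted over the list alone (camera adjusted p = 0.000521; adjusted p = 0.333 with an estimated correlation). Amino acid permeases averaged −0.50, 14 of 27 falling and 16 adjusted over the list alone, with DUR3 at −1.42, GAP1 at −1.40 and AGP1 at −1.05 (camera adjusted p = 2.9e-06; adjusted p = 0.0295 with an estimated correlation). Gcn4 targets averaged −0.31, 22 of 39 falling and 28 adjusted over the list alone, with LYS2 at −0.68, LYS4 at −0.59 and ILV6 at −0.56 (camera adjusted p = 3.7e-08; adjusted p = 0.201 with an estimated correlation).

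In the trisomic descent general stress genes averaged −0.53, 8 of 29 falling, with SPI1 at −2.65, DDR2 at −2.05 and XBP1 at −1.21 (camera adjusted p = 0.00521; adjusted p = 0.737 with an estimated correlation). Ribosomal proteins averaged 0.10, 39 rising against 34 adjusted over the list alone, with RPL39 at 0.52, RPS25B at 0.47 and RPL38 at 0.42 (camera adjusted p = 1.6e-05; adjusted p = 0.737 with an estimated correlation). Ribosome biogenesis averaged 0.21, 11 rising and 2 falling, with KRR1 at 0.65, SDA1 at 0.62 and BRX1 at 0.57 (camera adjusted p = 0.0212; adjusted p = 0.782 with an estimated correlation). Iron and copper uptake averaged −0.36, 11 falling and 14 adjusted over the list alone, with FIT1 at −0.84, FET3 at −0.67 and COT1 at −0.66 (camera adjusted p = 0.000521; adjusted p = 0.527 with an estimated correlation). Alkaline pH and calcineurin genes averaged −0.28, 8 of 25 falling, with RIM101 at −0.71 and YPS1 at −0.57 (camera adjusted p = 0.030; adjusted p = 0.201 with an estimated correlation). Hexose transporters averaged −0.44, 4 falling, with HXT5 at −1.91, MIG2 at −1.03 and HXT1 at −0.61 (camera adjusted p = 0.0372; adjusted p = 0.201 with an estimated correlation). Thiamine genes averaged −0.27, 8 falling and 1 rising, with THI72 at −1.16, THI73 at −0.77 and THI7 at −0.55 (camera adjusted p = 0.0238; adjusted p = 0.201 with an estimated correlation). Limma called 998 higher and 806 lower with the set term and 24 and 14 without it, all 38 shared. With quantile normalization repeated and no set term, 519 were higher and 242 lower, and a fit of the compared groups alone called 0.

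Set directly against the trisomic descent, the H2 line had ECM1 at least 44.4-fold higher (adjusted p = 1.7e-11), GRE1 higher by 3.57 ± 0.17 (SE, n = 2 against 2), the hexose transporter gene HXT5 by 2.94 ± 0.27, YPT53 of endosomal traffic by 2.93 ± 0.26 and PRM1 of cell fusion by 2.92 ± 0.14. MET17 was at least 295-fold lower (adjusted p = 1.0e-15), and SRL4, SNO1, RTC2 and FMP23 changed by −5.13, −4.96, −4.40 and −4.09. Gcn4 targets averaged −1.24, 37 of 39 falling on either scale, with ARG3 at −3.84, ARG1 at −2.93 and LYS1 at −2.73 (camera adjusted p = 2.9e-28; adjusted p = 0.0212 with an estimated correlation). The stress list averaged 0.91, 15 of 29 rising, SPI1 by 1.82 and MSC1 by 1.59, against 17 adjusted over the list alone (camera adjusted p = 8.1e-06; adjusted p = 0.645 with an estimated correlation). Heat shock chaperones averaged 0.42, 17 rising and 1 falling, HSP26 by 2.43, HSP42 by 1.48 and CUR1 by 0.85, against 18 and 1 adjusted over the list alone (camera adjusted p = 0.000545; adjusted p = 0.596 with an estimated correlation). The phosphate regulon averaged 0.59, 10 rising and 2 falling, with PHO89 at 2.25, PHO84 at 2.18 and PHO5 at 1.75 (camera adjusted p = 0.00814; adjusted p = 0.596 with an estimated correlation).

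Proteasome genes averaged 0.25 higher in the H2 line than in the trisomic descent, 23 rising and 26 adjusted over the list alone, with RPN3 at 0.53 and RPN10 at 0.48 (camera adjusted p = 4.1e-07; adjusted p = 0.295 with an estimated correlation). Glycolysis averaged 0.29, 10 rising, with PDC6 at 2.02, TDH1 at 1.47 and ENO1 at 0.63 (camera adjusted p = 0.00382; adjusted p = 0.596 with an estimated correlation). Ribosomal proteins averaged 0.07, 19 rising and 3 falling against 1 adjusted over the list alone, with RPL41A at 0.61 and RPL15B at 0.46 (camera adjusted p = 0.00116; adjusted p = 0.739 with an estimated correlation). Oxidative phosphorylation averaged −0.29, 9 falling, with ATP14 at −0.68, COX9 at −0.63 and SDH2 at −0.61 (camera adjusted p = 0.00582; adjusted p = 0.828 with an estimated correlation). Thiamine genes averaged −0.37, 8 falling and 2 rising, with THI72 at −1.54 and THI13 at −1.0 (camera adjusted p = 0.0216; adjusted p = 0.211 with an estimated correlation). Auxotrophic markers averaged −1.61, again mostly through MET17, 5 falling and 1 rising, with HIS3 at −1.32 and LYS2 at −1.02 (camera adjusted p = 0.00298; adjusted p = 0.208 with an estimated correlation). Limma called 1053 higher and 1057 lower with the set term and 69 and 155 without it, all 224 shared. The compared groups alone gave 797 and array weights 1074.

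The unevolved clones with 3 copies or 1 copy of chromosome III had 1 array each and were described without a test. The trisomic clone was higher than ancestor array 1 along the whole of chromosome III, from GEX1 to YCR108C in the gene order of R64, over 145 genes. Its largest changes were YGP1 at 2.78, SPI1 at 1.71, DDR2 at 1.48, GPH1 at 1.47 and FMP16 at 1.28, and ECM1 at least 79.3-fold lower, PTR2 of peptide uptake at −1.04, CNE1 at −0.90, RPS14B at −0.74 and AAP1 at −0.74. Among mating-type genes AGA2 stood at −0.45, ASG7 at −0.41, STE6 at 0.23, MF(ALPHA)1 at least 1.20-fold lower, MF(ALPHA)2 at −0.29, STE3 at 0.28, HMRA1 at 0.92, FUS1 at 0.71 and RME1 at −0.68. General stress genes had a median of 0.51 and Gcn4 targets 0.08, both at percentile 100 of 10000 random lists, ribosomal proteins −0.05 at percentile 0 and chaperones 0.05 at 99.94. In the monosomic clone PCK1 and FBP1 of gluconeogenesis stood at 2.41 and 2.23, YGP1 at 1.92, RGI1 at 1.53 and MLS1 of the glyoxylate cycle at 1.46. The transcription factor gene YAP3 stood at −3.50, YIR042C was at least 2.60-fold lower, and PAU8, PAU14 and PAU18 stood at −1.28, −1.22 and −1.20. Its mating-type genes gave STE2 at −0.35, MFA2 at −0.34, BAR1 at −0.30, STE3 at −0.60, MF(ALPHA)1 at −0.10, SAG1 at −0.05, RME1 at 0.82, KAR4 at −0.76 and HMRA1 at −0.65. The TCA and glyoxylate list had a median of 0.21 and oxidative phosphorylation 0.07, both at percentile 100. General stress genes stood at 0.08 and ribosome biogenesis at 0.05, at percentiles 99.89 and 99.72, and ergosterol genes at −0.07 and the vacuolar ATPase at −0.06, at 0.02 and 0.2.

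High pH was followed in haploid cells, and mating type differed between the arrays compared. Haploid ancestor 1 expressed alpha-specific genes, at a mean of 11.1 in log2 against 5.73 for a-specific genes, while haploid ancestor 2 expressed a-specific genes, at 11.8 against 7.01. All arrays of the pH line were of the a kind, with a-specific means of 9.50 to 10.6 after 750 generations. The spread behind the errors and calls at high pH comes mostly from the 8 spores of the 39 °C line in the same fit. Those spores differed in mating type and on chromosome III, so the spread is not only that between pH arrays. FRE7, a copper-regulated ferric reductase gene, rose by 3.44 ± 0.56 after 750 generations (SE, n = 4 against 1; adjusted p = 0.0403), and the copper transporter gene CTR1 by 1.54 ± 0.26 (adjusted p = 0.0479). RTA1 of membrane lipid export rose by 1.59 ± 0.18, the beta-lyase gene IRC7 by 1.26 ± 0.15 and REE1 by 1.26 ± 0.21. Smaller rises were those of LYS9 and LYS12 of lysine synthesis at 0.94 ± 0.13 and 0.49 ± 0.08 and of the low-affinity iron transporter gene FET4 at 0.80 ± 0.12.

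These 8 were the genes called at high pH, with 0 lower, although 396 were higher and 245 lower at an unadjusted p under 0.05. With no set term 11 were higher and 1529 lower, 5 of the 8 shared, with a median of −0.52 over all genes and LYS12 at −0.06. With quantile normalization repeated as well, 41 were higher and 30 lower. Leaving out array 1 of the group gave 56 genes, and leaving out array 2, 3 or 4 gave 3. The compared groups alone gave 17, all arrays in 1 fit 18 and array weights 1543. Haploid-specific genes had medians of −0.04, −0.11, −0.64 and −1.18 in arrays 1 to 4 over haploid ancestor 1, and without both arrays 3 and 4 the count was 2, an alternative chosen after the data were seen.

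No list member other than these was called over all genes at high pH, and each list below compares cells of opposite mating type. Ribosome biogenesis averaged −0.28 with all 38 genes negative, DBP2 at −0.75 and SPB4 at −0.49 ± 0.11, and 1 called adjusted over the list alone (camera adjusted p = 9.0e-15; adjusted p = 0.737 with an estimated correlation). The phosphate regulon averaged −0.57, with PHO89 at −2.75 ± 0.71, PHM6 at −1.61 ± 0.44 and 5 of 18 called adjusted over the list alone (camera adjusted p = 1.4e-08; adjusted p = 0.737 with an estimated correlation). Chaperones averaged 0.29, with CUR1 at 1.33 ± 0.63 and BTN2 at 1.28 ± 0.68 (camera adjusted p = 0.00115; adjusted p = 0.897 with an estimated correlation). Stress genes also averaged 0.29, with TSL1 at 1.01, HXK1 at 0.77 and 1 called adjusted over the list alone (camera adjusted p = 0.00149; adjusted p = 0.897 with an estimated correlation). Ribosomal proteins averaged −0.03, with RPL41A at −0.36 and RPS19A at −0.25 (camera adjusted p = 6.3e-05; adjusted p = 0.897 with an estimated correlation). The proteasome averaged 0.09, with PUP3 and RPN4 at 0.29 (camera adjusted p = 0.00407; adjusted p = 0.897 with an estimated correlation), and uracil and purine genes −0.13, with ADE4 at −0.44 and URA1 at −0.35 (camera adjusted p = 0.0150; adjusted p = 0.897 with an estimated correlation). The a-specific genes averaged 4.47, with MFA2 at 7.02 ± 2.10 and STE2 at 6.00 ± 1.76 (camera adjusted p = 6.1e-06; adjusted p = 0.737 with an estimated correlation). The alpha-specific genes averaged −5.15, with MF(ALPHA)1 at −7.86 ± 3.40 and MF(ALPHA)2 at −5.35 ± 2.19 (camera adjusted p = 0.00149; adjusted p = 0.737 with an estimated correlation). The 7 a-specific and 4 alpha-specific genes were each called adjusted over the list alone.

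Chromosome V was followed along the pH line because the disomic spore carries it in excess of the euploid spore. It lay at 0.76 in the disomic spore and 0.75 in the array after 150 generations, both over the euploid spore, along all 253 genes in the disomic spore. After 750 generations the arrays lay at 0.013, 0.0046, 0.27 and 0.34 over haploid ancestor 1. Their centred mean of 0.03 ± 0.17 (SD, n = 4) against −0.13 (n = 2) differed by 0.15, with p = 0.2 in an exact permutation test of 15 arrangements, which is more than the smallest possible, and 0.610 adjusted over chromosomes. Without array 4 the difference was 0.09. Arrays 3 and 4, the higher ones, were also those with low haploid-specific genes, at medians of −0.64 and −1.18. The genes of chromosome V averaged 0.19, with 217 of 253 positive and 0 called (camera adjusted p = 1.4e-08; adjusted p = 0.897 with an estimated correlation).

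The disomic spore and the array after 150 generations were each set against the euploid spore, without a test. That 1 array enters both differences, so any deviation of its own, such as 0.42 on the centred scale over the 48 genes from CPR6 to DCS1, moves both alike, and their likeness was not tested. FRE7 stood at 4.49 and 3.95, the spore-wall gene CRR1 at 3.23 and 3.26, REE1 at 1.96 and 2.06 and the ferric reductase gene FRE1 at 1.93 and 1.97, in that order. YER034W stood at 1.94 in the disomic spore, and MIG3 at 2.12 after 150 generations. HSP30 stood at −3.27 and −2.29, and the iron-siderophore wall genes FIT2 at −2.88 and −2.59 and FIT3 at −2.38 and −2.33. The disomic spore also had TIS11 at −2.46 and PHO89 at −2.35, and the array after 150 generations had PTR2 at −2.16 and YGR109W-A at −1.97. General stress genes had medians of −0.40 in the disomic spore and −0.56 after 150 generations, the phosphate regulon −0.41 and −0.22 and the TCA list −0.29 and −0.26, all at percentile 0. Iron and copper uptake lay at −0.32 and −0.17, at percentiles 0 and 0.01, and oxidative phosphorylation at −0.29 and −0.13, at 0 and 0.05. Also at percentile 0 were methionine and sulfur genes at −0.32 in the disomic spore and uracil and purine genes at −0.32 after 150 generations, while a-specific genes lay at −0.48 and −0.56, both at 0.01. Less extreme were permeases at −0.15 and haploid-specific genes at −0.16 in the disomic spore, at 0.16 and 0.23, and alkaline pH genes at −0.13 after 150 generations, at 0.13. In the disomic spore AGA2, ASG7 and MFA1 stood at −0.83, −0.80 and −0.79, STE3 at −0.77, SAG1 at 0.38, MF(ALPHA)2 at −0.22, NEJ1 at 0.64, PRM2 at −0.56 and AGA1 at −0.55. After 150 generations MFA1 stood at −1.63, AGA2 at −1.51, ASG7 at −0.94, MF(ALPHA)2 at −0.38, STE3 at −0.37, SAG1 at 0.09, AGA1 at −1.39, FUS1 at −1.27 and PRM1 at −0.81.

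Spores of the 39 °C line were compared with the haploid ancestor, in gene fits with array 2, of the a kind. Their mating type and chromosome III varied, and both enter the results below. Spore 3 expressed a-specific genes at a mean of 11.3, and the other 7 at 6.20 to 6.75. Alpha-specific means were 12.1, 12.5, 12.3 and 10.7 in spores 2, 4, 6 and 8, and 7.22, 6.85, 7.99 and 7.59 in spores 1, 3, 5 and 7. Haploid-specific means in spores 1 to 8 were 7.69, 9.84, 9.45, 9.94, 7.71, 9.85, 7.61 and 9.45. Chromosome III lay at 0.79, 0.79, 0.02, 0.0046, 0.76, 0.01, 0.80 and 0.0048 over haploid ancestor 2 in that order, with a centred mean of 0.24 ± 0.43 (SD, n = 8) against −0.18 ± 0.02 (SD, n = 2). The difference of 0.42 had p = 0.222 in an exact permutation test of 45 arrangements and 0.427 adjusted over chromosomes.

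**Figure D2:**
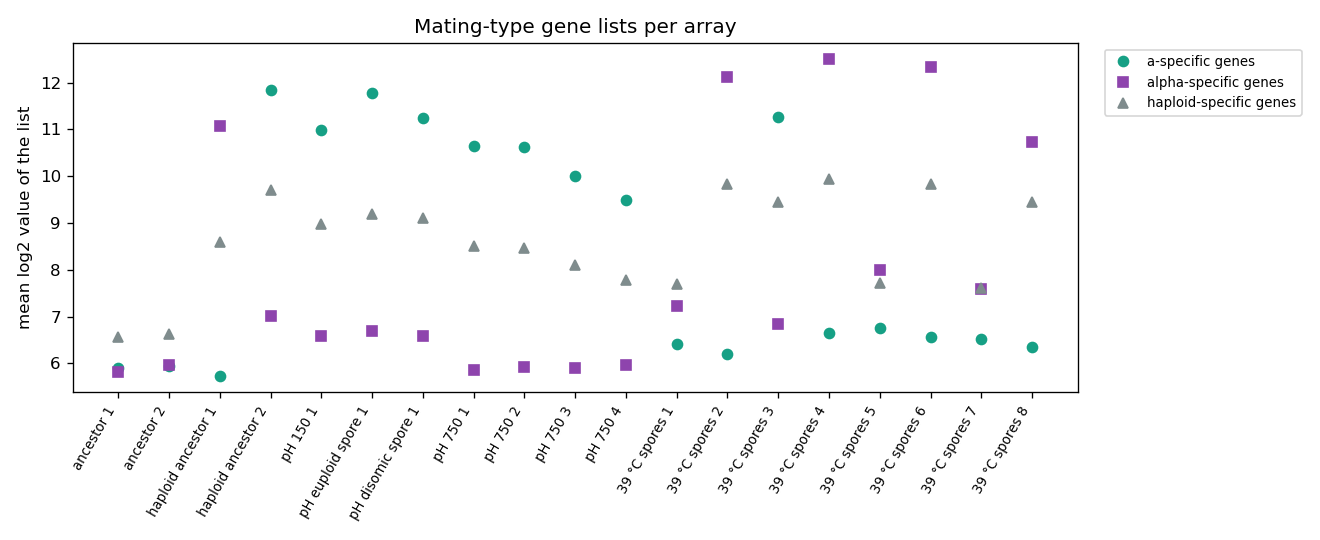
Mean log2 value of the a-specific (circles), alpha-specific (squares) and haploid-specific (triangles) genes on each array of the diploid and haploid ancestors, the pH line and the spores of the 39 °C line, 1 array per position. Haploid ancestor 1 shows alpha-specific genes at 11.1, haploid ancestor 2 a-specific genes at 11.8 and spore 3, alone of its line, at 11.3.

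In the 39 °C spores limma called 0 genes with the set term, with 318 higher and 356 lower at an unadjusted p under 0.05, while 3318 were higher and 2 lower without the term and a random set term gave 0. Array weights gave 750 and all arrays in 1 fit 5. The smallest p-values upward were those of COR1 of the cytochrome bc1 complex at 0.49 ± 0.08 (SE, n = 8 against 1), COX4 of cytochrome oxidase at 0.32 ± 0.05 and the NADH dehydrogenase gene NDE1 at 0.43 ± 0.07, each with an adjusted p = 0.0699. Downward they were those of the carbonic anhydrase gene NCE103 at −0.51 ± 0.10, MET1 at −0.32 ± 0.07 and SEC39 at −0.26 ± 0.06. Leaving out spore 4 gave 27 genes and leaving out spore 3 gave 12. Quantile normalization repeated without the set term gave 281 higher and 239 lower.

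Oxidative phosphorylation genes averaged 0.37 in these spores with 36 of 37 positive, SDH2 at 0.82 ± 0.16 and SDH1 at 0.81 ± 0.23, and 30 were called adjusted over the list alone against 0 over all genes (camera adjusted p = 5.8e-29; adjusted p = 0.505 with an estimated correlation). Cell wall genes averaged 0.24, with YPS3 at 1.03 ± 0.63, PIR3 at 0.68 and 3 called adjusted over the list alone (camera adjusted p = 2.4e-07; adjusted p = 0.865 with an estimated correlation). Methionine and sulfur genes averaged −0.20, with MMP1 at −0.56 ± 0.17, STR3 at −0.55 and 3 called adjusted over the list alone (camera adjusted p = 0.00122; adjusted p = 0.865 with an estimated correlation). The TCA list averaged 0.28, with FBP1 at 1.31 ± 0.81 and MLS1 at 0.76 (camera adjusted p = 0.000425; adjusted p = 0.865 with an estimated correlation). The a-specific genes averaged −4.75, with MFA2 at −6.51 ± 1.99, AGA2 at −5.88 ± 1.68 and all 7 called adjusted over the list alone (camera adjusted p = 9.3e-07; adjusted p = 0.865 with an estimated correlation). General stress genes averaged 0.39, with TSL1 at 1.13 ± 0.45 and DDR2 at 0.94 (camera adjusted p = 2.5e-06; adjusted p = 0.918 with an estimated correlation). The phosphate regulon averaged −0.39, with PHO11 at −1.76 ± 0.75 and PHO89 at −1.47 ± 0.67 (camera adjusted p = 0.000952; adjusted p = 0.918 with an estimated correlation). Ribosome biogenesis averaged −0.19, with NOP7 at −0.46 and IMP4 at −0.40 (camera adjusted p = 1.3e-05; adjusted p = 0.976 with an estimated correlation). Ribosomal proteins averaged 0.01, with RPL9B at 0.14 and RPL40B at 0.13 (camera adjusted p = 0.0297; adjusted p = 0.976 with an estimated correlation), and chromosome III averaged 0.36 with 133 of 146 genes positive (camera adjusted p = 4.2e-09; adjusted p = 0.976 with an estimated correlation).

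Across the 10 comparisons fixed before the data were examined, camera made 76 calls of lists and chromosomes, of which 6 held with an estimated correlation. Fry made 58 calls, and 25 of camera's 76 were among them. Ergosterol, haploid-specific and meiosis genes were called in none of them. Against 30 °C, abrupt heat gave ergosterol genes a camera adjusted p = 0.205 and meiosis genes 0.340, and gradual heat gave haploid-specific genes a camera adjusted p = 0.123 against the ancestor.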

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

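The tests of a broad rise and of other array splits, and the comparison of the minimal-medium groups, were chosen after the results were seen. The fit without the set term was as first designed. The correlation of the ancestor arrays was fixed before its value was seen.

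Abrupt and gradual heat differed by 0.50 on chromosome III, with every abrupt-heat array above every gradual-heat array. The count of genes that differed between these groups depended on the set term: 1 gene was called with it, and 2215 higher against 5 lower without it. Separately normalized sets would carry differences between sets into this contrast. Across 5335 genes, which are not independent replicates, ancestor array 1 minus array 2 correlated with abrupt minus gradual heat at r = 0.652 without the set term, so separate normalization is a candidate explanation of part of the excess of higher calls. The ancestor arrays differed by a median of 0.13 against 0.51 for the contrast, and only abrupt-heat replicate 2 shares a set with ancestor array 1. Sets without an ancestor array hold the other 3 replicates, so for them this test decides nothing. A broad rise of expression cannot be told apart from separate normalization, since the median after quantile normalization of all arrays, 0.0074, is fixed near 0 by that step. Over all 35 splits of the 8 arrays into 4 and 4, the real split called 1 gene and the highest other 0. That gene, MET17, was below background in both groups, and the count was 0 under 4 other settings, so the splits exclude nothing about chance. Without the set term the real split called 2220 genes and the highest other 166, but these splits exchange arrays across sets, and no set holds both groups.

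For the H2 arrays kept at 30 °C against abrupt heat, 1 of 35 splits, the real one, reached 95 genes, and the highest other reached 50. Without the set term the real split called 118 genes and the highest other 22. These splits exchange arrays across sets, whereas with the set term the contrast rests on 1 abrupt-heat array and 4 H2 arrays of 1 set, whose 5 arrangements are too few for a share under 0.05. The count was 1 with the compared groups alone, 3 with all arrays in 1 fit and 0 with replicate and set blocks.

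On minimal medium, 2110 genes differed between the H2 line and the trisomic descent, a test of the difference itself. Probe sets without a gene name, which no comparison above uses, also changed. On minimal medium 141 of 576 such probe sets were called in the H2 line, 75 higher and 66 lower, and 67 in the trisomic descent, 33 higher and 34 lower. Between these groups 99 were called, 52 higher and 47 lower. The H2 arrays kept at 30 °C had 1 against the ancestor, and the spores of the 39 °C line had 7 of 537, 6 higher and 1 lower.

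In 3 of 34 groups of values checked, 24 of named genes and 10 of chromosomes, 1 array lay far from the others, and chance gives about 1 in 20. COS12 was at 7.75 in gradual-heat replicate 1 against 7.49 to 7.51 in the others. RPS14B was at 12.7 in H2 replicate 4 against 12.87 to 12.90, and LYS2 at 10.2 in H2 replicate 3 against 10.36 to 10.38.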

How the results depend on the processing

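The set term, fixed, random or beside the replicate block, was chosen after the data were seen. So were quantile normalization repeated without the set term, the combined control, the fit without high pH arrays 3 and 4, the values within sets and the added comparisons. Other settings, no set term among them, were fixed beforehand. Of 164 named-gene results, the call remained in 162 with no filter on dim genes, 164 with the set as a random term, 158 with centring on the median, 157 with no trend, 154 with quantile normalization repeated, 156 with array weights and 133 with all arrays in 1 fit. It remained in 72 without the set term, in 121 with quantile normalization repeated as well, in 66 of 160 with the compared groups alone and in 0 of 10 with replicate and set blocks. Leaving out 1 array kept 505 of 565 named-gene calls and 2518 of 2535 list calls. Estimating the correlation left 6 of 76 list calls. Background limits MET17, ECM1, GAC1 and AGA2, whose low groups are bounds.

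The count for abrupt against gradual heat was 0 with a filter on the mean over arrays, with quantile normalization repeated, with median centring and with the probe set of highest mean. Array weights, which let the fit discount single arrays, raised counts to 331 for abrupt heat, 90 for gradual heat and 332 for 30 °C against the ancestor, 1144 for abrupt heat against 30 °C, 243 for abrupt against gradual heat, 480 for H2 at 30 °C against abrupt heat and 107 against the ancestor. They gave 1074 between the minimal-medium groups, 1543 at high pH and 750 in the spores. All arrays in 1 fit gave, for the first 4 of these comparisons in that order, 3, 2, 2 and 36, then 3 for H2 at 30 °C against abrupt heat, 18 at high pH and 5 in the spores. A fit of the compared groups alone, with fewer arrays, gave 0 for abrupt heat against the ancestor and against 30 °C, 446 for gradual heat, 1 for H2 at 30 °C against abrupt heat and 1 against the ancestor. It gave 1338 for H2 and 0 for the trisomic descent on minimal medium, 797 between them and 17 at high pH. The ancestor and 30 °C arrays as 1 control gave 110 genes for abrupt heat. The cause was not tested for any of these changes.

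No set term gave counts of 2 for gradual heat, 23 for 30 °C, 1 for abrupt heat against 30 °C, 2220 for abrupt against gradual heat, 508 and 38 for H2 and the trisomic descent on minimal medium, 224 between them, 2 for H2 at 30 °C against the ancestor, 1540 at high pH and 3320 in the spores. With quantile normalization repeated as well they were 72 for abrupt heat, 2 for gradual heat, 421 for 30 °C, 358 for abrupt heat against 30 °C, 731 for abrupt against gradual heat and 252 for H2 at 30 °C against abrupt heat. They were then 2 against the ancestor, 761 for the trisomic descent, 1266 between the minimal-medium groups, 71 at high pH and 520 in the spores, where the repeat with the set term gave 1. A random set term gave 57 for abrupt heat, 3 for 30 °C, 129 for abrupt heat against 30 °C, 4 for abrupt against gradual heat, 159 for H2 at 30 °C against abrupt heat and 9 against the ancestor. The high pH fit without arrays 3 and 4, whose haploid-specific genes were low, gave 2. PHO11, SPS4 and YOL014W turned to −0.25, −0.13 and −0.14 without the set term, with or without the replicate block, and LYS12 to −0.055. The fitted value of MET17 in abrupt against gradual heat, which has no direction since both groups were below background, was −0.10 with quantile normalization repeated as well. Ribosomal proteins in the spores turned with quantile normalization repeated (camera adjusted p = 0.995). The cause was not tested.

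With the replicate number as a block and no set term, abrupt against gradual heat called 1147 genes and H2 at 30 °C against abrupt heat 38. With the set term added the second gave 0, and the first, sharing no set, was not run. Same-numbered arrays correlated across genes at 0.0997, 0.170, 0.0273 and 0.110 in the first, above other numbers for replicates 1 and 4 only. The second gave −0.182, −0.238, −0.0458 and −0.190, each below another number. Pairing was undecided, as abrupt-heat arrays span 3 sets. Chromosome III of the trisomic and monosomic clones was 0.48 and −0.45 by the mean, 0.46 and −0.48 with no filter, 0.46 and −0.45 with quantile normalization repeated, and 0.48 and −0.50 without chromosome ends. Within shared sets, chromosome III shifted by 0.50 in abrupt heat, −0.51 in H2 at 30 °C and 0.40 in the spores, and chromosome V by 0.15 at high pH.

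Leaving out 1 array gave 16 genes throughout for abrupt heat, 3 to 4 for gradual heat, 1 throughout for 30 °C, 75 to 81 for abrupt heat against 30 °C and 0 to 1 for abrupt against gradual heat. It gave 61 (without H2 replicate 3) to 121 for H2 at 30 °C against abrupt heat and 3 to 10 (without replicate 4) against the ancestor. High pH gave 3 to 56, and the spores 0 to 27. List calls ranged from 53 without abrupt-heat replicate 2 to 87, but 53 covers fewer comparisons than the 76, since those that rest on that array then have no value. Chromosome III shifts ranged from 0.46 to 0.48 for abrupt heat, 0.49 to 0.51 against gradual heat, −0.49 to −0.46 for H2 at 30 °C, 0.49 to 0.50 and −0.51 to −0.48 in the clones and 0.35 to 0.47 in the spores, and chromosome V at high pH from 0.09 to 0.20. No value could be had without the lone array that ties 2 groups within a set. Abrupt heat, 30 °C and the ancestor are tied so, and leaving out their other arrays moves only the spread.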

Other observations

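The genes given by array, the stretches of neighbouring genes, the 3 tests of MET17 by regime, pathway and genotype, and the high pH tests of diploid RNA and of the list without the mating-type loci were chosen after the data were seen. The tests of array normalization and of the whole haploid-specific list were fixed before their values were seen.

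Genes under mating-type control varied among spores of the 39 °C line. GPA1, the pheromone G protein, was at 7.10, 7.36 and 7.06 in spores 1, 5 and 7 and at 11.07 to 11.46 in the others. HO, the mating-type switching endonuclease, was at 5.77, 6.23 and 5.96 in those spores and at 11.44 to 11.70 in the others. IME4, an inducer of meiosis, was at 8.79, 8.37 and 8.56 there, near its 7.08 to 8.56 in diploid arrays, and at background, 4.40 to 4.56, in the others. On chromosome III spores 1, 5 and 7 lay at 0.79, 0.76 and 0.80, and spore 2, with higher GPA1, at 0.79.

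FRE7 was at 6.71 in haploid ancestor 1, 7.53 in haploid ancestor 2 and 6.92 in the euploid spore. It was at 10.87 after 150 generations at high pH, 11.41 in the disomic spore, and 10.15, 9.99, 10.14 and 10.32 after 750 generations. ECM1 was at 3.90 in the trisomic clone and 3.99 and 3.88 in its descent on minimal medium, all below background, and at 9.39 to 11.41 on the other diploid arrays. YAP3 was at 4.74 in the monosomic clone and at 7.86 to 9.13 elsewhere.

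Some stretches of neighbouring genes, in the gene order of R64, stood apart on 1 or 2 arrays. On chromosome IV, the 54 genes from SSF2 to YPR1 were at 0.40 in abrupt-heat replicates 1 and 3 on the centred scale. The 53 from TFB1 to ESF1, which overlap them, were at 0.41 and 0.42. These 2 arrays alone make up their normalization set, so a difference of that set cannot be told apart from one of the replicates. On chromosome XII, the 53 genes from FKS1 to DUS3 were at 0.43 in abrupt-heat replicate 3 and 0.35 in array 1 of the trisomic descent. The 117 from CQD2 to STE23 were at 0.33 in that array 1, against 0.04 in array 2. The 34 genes from SCD6 to MET16 on chromosome XVI were at −0.38 in that same array 1. The euploid pH spore was at 0.42 over the 48 genes from CPR6 to DCS1 on chromosome XII. On minimal medium the ancestor array was at −0.41 over the 30 genes from BAP2 to YBR096W on chromosome II, and at −0.38 and −0.37 over the 34 from OCT1 to YJU3 and the 47 from TGL1 to CYT2 on chromosome XI.

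Haploid-specific genes were low in arrays 3 and 4 after 750 generations at high pH, with medians of −0.64 and −1.18 over haploid ancestor 1. Arrays 1 and 2 had −0.04 and −0.11. Chromosome V was higher in arrays 3 and 4, at 0.27 and 0.34. The list's percentile among random lists, 0 in arrays 3 and 4 against 2.99 and 0.19 in arrays 1 and 2, only re-ranks its median. It decides nothing about array normalization. MET17, at −0.82 relative to background, argued against RNA of the diploid ancestor. The list's correlation with the diploid profile was 0.0173 at its lower and met the preset bound against cells with both mating types. That bound was wrong, because haploid ancestor 1 is of the other mating type, and HMLALPHA1 and HMRA1 differed from it in all 4 arrays, HMLALPHA1 by −6.81, −6.75, −5.54 and −5.36 and HMRA1 by 6.33, 6.36, 6.22 and 5.99. Without those 2 loci the lower correlation of arrays 3 and 4 was 0.751, which is consistent with some cells of both mating types, while arrays 1 and 2 gave 0.048 and 0.177, and IME4 was at 3.99, 4.07, 6.64 and 7.08 in arrays 1 to 4.

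MET17 was above background on 7 arrays, those of the diploid ancestor, the unevolved trisomic and monosomic clones, the ancestor on minimal medium and the trisomic descent, and at or below background on the other 33. Evolution at high temperature was argued against by the 30 °C arrays, of which the higher lay at −0.37 relative to background, and lower expression of the whole sulfur pathway by its other 22 genes, with a median of 0.024 in gradual heat. A marker genotype that differs between strains may be the source, but 0 groups held both states, so genotype and line of descent cannot be told apart. LYS2, another common marker, rose by 0.85, 0.63 and 0.98 in abrupt heat, gradual heat and H2 against the ancestor. On minimal medium it changed by −1.70 in the H2 line and −0.68 in the trisomic descent.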
